A study of Mus musculus with 6 samples.

How the data were processed

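Liver RNA from 6 mice was sequenced, 3 Cyp2e1-/- (knockout) and 3 Cyp2e1+/+ (wild type). The labels give the strain as C57BL/6 and an age of 22 weeks for both genotypes, and the series design adds a high-fat diet of 14 weeks. Per the labels' protocols, total RNA was extracted from homogenized liver with a Qiagen miRNeasy kit and libraries were made with an Illumina TruSeq RNA kit. Whether counting used the strand is not given in the sources used here, so overlapping and antisense genes were not told apart.

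The submitters' processing notes name HISAT and the genome build mm10. The program that made the expression values, its version and its annotation are not given in the sources used here. The deposited values are FPKM (fragments scaled to transcript length and library size) per the file headers, given to 2 decimals for 15960 genes, with the authors' gene identifiers, symbols and transcript accessions. Of these, 3607 genes also carried transcripts named as new by the authors. No gene was at 0 in all 6 samples, and 1595 to 1909 genes per sample were listed at 0. Positions came from the RefSeq annotation of GRCm38, the assembly that mm10 names, with 15915 genes matched by identifier.

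FPKM values carry no counts, so no count model was used. Before the data were examined the plan was a count test if the table held counts, and otherwise limma on FPKM, and the second course was followed. Samples were grouped by the genotype label. The test was limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3 on log2(FPKM + 1), for genes with at least 1 FPKM in at least 3 of the 6 samples. It gave 9968 tested genes. P-values were adjusted over these genes by Benjamini-Hochberg, and a gene was said to rise or fall when its adjusted p was under 0.05. Fold changes are knockout minus wild type on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Group values are the mean FPKM ± SD. The labels number the samples but do not say how they were taken, and the p-values measure the spread between these samples.

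Also fixed before the data were examined were 29 gene lists, the rule for named genes, and most of the alternatives. The lists cover PPARα targets, mitochondrial beta-oxidation, fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, bile acids, xenobiotic P450s, glutathione and NRF2 response, antioxidant enzymes, stress response, glucose metabolism, lipid droplets, hepatokines, acute phase, oxidative phosphorylation, circadian clock, male-biased and female-biased liver genes, pericentral and periportal hepatocyte zones, cell cycle, and 40 neighbours of Cyp2e1 on chromosome 7. Further lists hold markers of macrophages, lymphocytes and neutrophils, stellate cells, sinusoidal endothelium, cholangiocytes, red blood cells, adipose tissue and pancreas. Of 567 list entries, 539 were in the table. Each list with at least 3 tested genes was tested with camera from limma at its preset correlation of 0.01, adjusted by Benjamini-Hochberg over 27 lists. Camera with an estimated correlation and fry stand beside it. With an estimated correlation camera takes its degrees of freedom from the samples and not the genes. With 6 samples it therefore has little power. Counts of genes adjusted over the list alone use the same p-values.

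Named genes are Cyp2e1, then the 8 largest rises and 8 largest falls among genes past the threshold whose knockout values all lay on the same side of the wild type values, with a mean of at least 1 FPKM in a group, leaving out unnamed transcripts. For each list they are up to 4 genes past the threshold with the smallest adjusted p, or, where none passed, the 2 tested members with the highest FPKM. Any other gene named was chosen after its values were seen, and 2 genes that the rule takes are not reported here.

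Depth is not stated in the table. Low values of short genes (transcripts of 450 to 1200 bases) fell on steps, and 73.3% to 77.1% of 186 to 207 such values per sample lay within 0.15 of a whole step, against 30% by chance. The steps were fitted to the same values. They put the depth at about 12.1 M fragments for knockout replicate 1 and between 9.21 and 9.85 M for the other 5 samples, so that 1 FPKM over 1 kilobase stands for about 9 to 12 fragments. These are estimates from the steps, and no count test was run on them.

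The replicate numbers come from the sample titles. Whether they pair the samples was checked with the correlation, over tested genes, of each sample's deviation from its group mean. It was 0.30 for replicates 1, 0.20 for replicates 2 and 0.157 for replicates 3, all above 0.1, although knockout replicate 3 correlated more with wild type replicate 2 (0.212). Deviations from a group mean sum to 0, so the values for replicates 2 and 3 are not independent of that for replicates 1. They are not separate evidence of pairing. As all were above 0.1, the samples were treated as paired by number in an alternative, with the replicate as a block, and its value is given where it changed a call.

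The alternatives fixed beforehand were no filter, a mean of at least 5 FPKM, a pseudocount of 0.1, median-ratio scaling, sample quality weights, the replicate block, a minimum change of 1.2-fold and leaving out each sample. Added after the data were seen were equal sums, replicate 1 as a covariate, both replicate 1 samples left out, and chromosome 4 left out. The pipeline was tested on simulated data of 9968 genes with 200 genes changed between knockout and wild type. It recovered 17.9% of genes changed by 0.5 on the log2 scale, 97.0% of those changed by 1 and 100% of those changed by 2, with 11 false calls, and none of 20 unchanged lists was called. The simulated genes varied independently of each other, while the estimated correlation within the real list of PPARα targets was 0.51. The simulation therefore cannot show how often camera at the preset correlation calls unchanged lists of correlated genes.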

Results

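CYP2E1 is a cytochrome P450 of hepatocytes that oxidizes small molecules such as ethanol and acetone, and PPARα is the nuclear receptor that drives fatty acid oxidation in liver. The series is about the interplay of the 2 proteins in obesity, and the comparison made here asks how the hepatic transcriptome differs between Cyp2e1-/- and Cyp2e1+/+ mice after 14 weeks of high-fat diet (n = 3 libraries per genotype). The libraries summed to 562590 to 624264 FPKM and held 9628 to 9963 genes at 1 FPKM or more. Major urinary protein genes took 22.95% to 26.7% of the sum, and the 10 most abundant genes took 37.7% in knockout replicate 1 against 32.5% to 33.5% in the other samples.

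Cyp2e1 (gene 13106, chromosome 7, 140763819 to 140774990, GRCm38) fell to 257 ± 12.0 FPKM in the knockout from 6480 ± 823 in the wild type (SD, n = 3 each). The knockout libraries held 254, 247 and 271 FPKM and the wild type libraries 7427, 5942 and 6071. The log2 fold change was -4.64 (SE 0.14; limma, adjusted p = 6.7e-08), and the knockout kept 0.0397 of the wild type level. A gene-level table does not show whether these fragments came from a disrupted allele or from sequence shared with other genes. Of 9968 genes tested, 47 rose and 29 fell in the knockout (limma, Benjamini-Hochberg), and 51 of these 76 changed by at least 1 on the log2 scale. At an unadjusted p under 0.05 there were 990 genes. In all 76 the knockout and wild type values did not overlap, which also held for 15.4% of tested genes, against 10% by chance. The count depended on the libraries used: it was 211 without knockout replicate 1, 29 without knockout replicate 2, 37 without knockout replicate 3, 117 without wild type replicate 1 and 32 without wild type replicate 2 or wild type replicate 3. Without replicate 1 of both genotypes, which stood apart from the rest, it was 1183, and these included all 76.

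The largest rise was in C8a, which encodes the alpha chain of complement component 8 (gene 230558, chromosome 4, 104815679 to 104876487). It went from 1.36 ± 0.33 FPKM in wild type to 217 ± 24.6 in the knockout, a log2 fold change of 6.54 (SE 0.15; limma, adjusted p = 1.1e-08). The metal-binding protein gene Mt2 rose from 25.7 ± 9.61 to 171 ± 28.7 FPKM, and Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 3.57 ± 1.01 to 15.8 ± 4.17. The zinc-finger genes Zfp970 (0.26 ± 0.095 to 16.7 ± 2.50 FPKM) and Zfp971 (0.0967 ± 0.065 to 3.07 ± 1.14), which share sequence with each other and with neighbours, rose as well. So did the chemokine gene Ccl27a (0.74 ± 0.64 to 7.0 ± 1.63), the acetyltransferase gene Nat8f5 (0.717 ± 0.28 to 6.68 ± 2.59) and Psmc3ip (0.357 ± 0.13 to 4.37 ± 2.84). Leaving out knockout replicate 2, wild type replicate 2 or wild type replicate 3 ended the call of Psmc3ip (limma, adjusted p = 0.081, 0.087 and 0.12, against 0.026 with all samples). Without the filter on low values Nat8f5 and Psmc3ip did not pass (limma, adjusted p = 0.051 and 0.14).

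Next to Cyp2e1, the largest fall among genes with a name was in Asns, the asparagine synthetase gene (gene 27053, chromosome 6, 7675165 to 7693209), from 10.7 ± 4.13 FPKM in wild type to 0.647 ± 0.17 in the knockout (log2 fold change -2.78, SE 0.23; limma, adjusted p = 3.2e-04). Alas2, the erythroid enzyme of heme synthesis (gene 11656, chromosome X, 150547417 to 150570622), fell from 47.9 ± 3.30 to 9.43 ± 0.86 FPKM (log2 fold change -2.23, SE 0.13; limma, adjusted p = 2.0e-05). Hsd3b5, a steroid dehydrogenase gene of male liver, fell from 80.7 ± 11.1 to 24.3 ± 11.3 FPKM, and Orm3, an orosomucoid gene, from 17.0 ± 3.68 to 5.44 ± 2.82. Zfp991 fell from 6.52 ± 1.23 to 1.88 ± 0.31 FPKM, the annexin gene Anxa5 from 15.7 ± 1.07 to 6.26 ± 1.92, and the ion channel gene Hcn3 from 3.66 ± 0.71 to 1.08 ± 0.18. The calls of 4 of these rested on particular libraries. Hsd3b5 lost its call without knockout replicate 2, wild type replicate 1, 2 or 3 (limma, adjusted p = 0.071, 0.056, 0.14 and 0.16). Orm3 lost it without knockout replicate 2 or 3 or wild type replicate 1, 2 or 3 (0.16, 0.14, 0.091, 0.057 and 0.17), Anxa5 without knockout replicate 2 or wild type replicate 2 or 3 (0.091, 0.059 and 0.086), and Hcn3 without knockout replicate 2 or wild type replicate 2 (0.064 and 0.059).

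**Figure D1:**
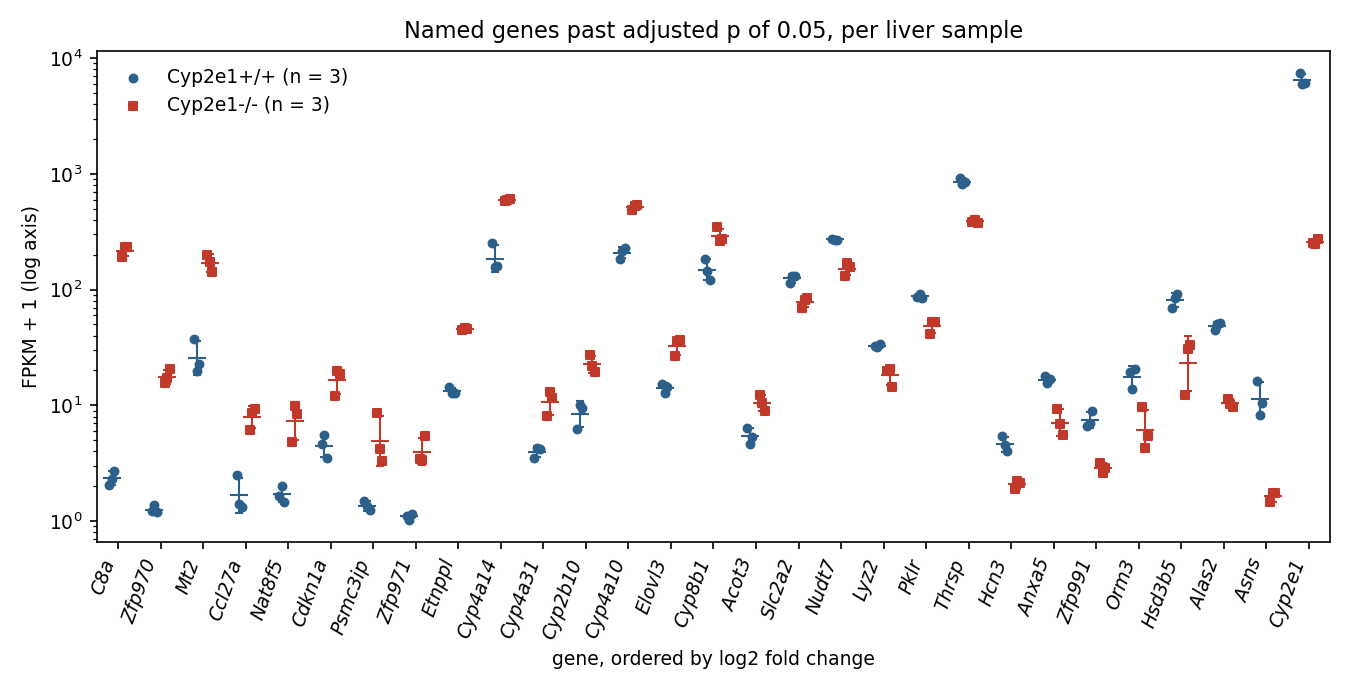
FPKM + 1 on a log axis for the 29 named genes past the threshold, ordered from the largest rise to the largest fall, with a point for each of 3 wild type (blue circles) and 3 knockout (red squares) livers; horizontal ticks are means and bars 1 SD, both on the log2 scale. C8a lies near 1 to 2 FPKM in wild type and at 189 to 232 FPKM in the knockout, and Cyp2e1 at 5942 to 7427 and 247 to 271 FPKM.

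PPARα targets were higher in the knockout. Of 25 tested targets 4 rose, none fell and 21 did not pass, and 22 of 25 had a positive fold change. When adjusted over the list alone, 8 rose. The 4 were Cyp4a10 (209 ± 22.1 to 518 ± 30.1 FPKM), Cyp4a14 (188 ± 54.8 to 596 ± 12.8) and Cyp4a31 (2.99 ± 0.43 to 9.95 ± 2.59), fatty acid omega-hydroxylases that lie side by side on chromosome 4, and the acyl-CoA thioesterase gene Acot3 (4.45 ± 0.90 to 9.55 ± 1.69). Cyp4a10 and Cyp4a31 share 26.5% of their 31-base words, so reads may have been divided between them. The list had a median log2 fold change of 0.35 and passed camera (adjusted p = 1.9e-08), but not with an estimated correlation (adjusted p = 0.70 with an estimated correlation). The level of the list in knockout replicate 1 (-0.14 from the mean of all samples on the log2 scale) lay among the wild type levels (-0.23 to -0.11), while knockout replicates 2 and 3 stood at 0.38 and 0.40. Without knockout replicate 3 the median was 0.22, and without replicate 1 of both genotypes 0.52. The list was lower in replicate 1 of both genotypes than in the other samples (median -0.28; camera, adjusted p = 0.035), a contrast in which no list passed with an estimated correlation (lowest adjusted p = 0.28). Acot3 lost its call without knockout replicate 1, 2 or 3 or wild type replicate 2 or 3 (limma, adjusted p = 0.055, 0.21, 0.066, 0.20 and 0.17), and Cyp4a31 without knockout replicate 2 (0.064).

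None of 30 oxidative phosphorylation genes passed, over all genes or adjusted over the list alone, but 28 had a positive fold change, with a median of 0.14, and the list passed camera upward (adjusted p = 0.0012; adjusted p = 0.72 with an estimated correlation). Its most abundant members were Atp5b (607 ± 13.4 against 551 ± 28.1 FPKM in wild type) and Cox4i1 (535 ± 48.4 against 539 ± 97.9). The level of the list in wild type replicate 1 (0.11) lay among the knockout levels (-0.037 to 0.13). The call was lost without wild type replicate 2 (camera, adjusted p = 0.14). The median was 0.21 without wild type replicate 1 and 0.28 without replicate 1 of both genotypes. The list also differed between replicate 1 and the other samples (camera, adjusted p = 0.012, upward), but the genotypes went opposite ways. Knockout replicate 1 (-0.037) lay below knockout replicates 2 and 3 (0.13 and 0.088). Wild type replicate 1 (0.11) lay above wild type replicates 2 and 3 (-0.18 and -0.12). None of 18 genes of mitochondrial beta-oxidation passed on either count (median 0.099; camera, adjusted p = 0.12). Acaa2 stood at 633 ± 70.4 and 610 ± 85.1 FPKM in knockout and wild type, and Acadm at 342 ± 9.86 and 313 ± 24.7. This list passed without wild type replicate 1 (median 0.16; camera, adjusted p = 0.0054), without replicate 1 of both genotypes (median 0.19; camera, adjusted p = 0.0035), with sample quality weights (camera, adjusted p = 0.0044) and with no filter on low values (camera, adjusted p = 0.049). With an estimated correlation none of these passed (adjusted p = 0.61 to 0.79). Its median was 0.047 without knockout replicate 2, 0.059 without knockout replicate 3 and 0.044 without wild type replicate 2 (camera, adjusted p = 0.28, 0.10 and 0.55).

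Among genes of fatty acid and triglyceride synthesis, Thrsp, a lipogenic regulator, fell from 859 ± 53.2 to 389 ± 11.7 FPKM (log2 fold change -1.14, SE 0.12; limma, adjusted p = 0.0014), and 17 of 18 did not pass. Adjusted over the list alone, 3 fell: Thrsp, Fasn (12.3 ± 1.64 FPKM in wild type, 7.42 ± 1.16 in the knockout) and Elovl6 (4.67 ± 1.97 and 1.86 ± 0.28). As a list they did not differ (camera, adjusted p = 0.32). Among genes of glucose metabolism and insulin signalling, Pklr, the liver pyruvate kinase, fell from 86.9 ± 4.20 to 47.7 ± 6.22 FPKM and Slc2a2, the liver glucose transporter, from 124 ± 10.2 to 77.2 ± 8.0, and 15 of 17 did not pass. With the replicate as a block Slc2a2 had an adjusted p of 0.0505 (limma). Adjusted over the list alone, 2 of them rose and 4 fell. The list did not pass (camera, adjusted p = 0.93); its median was 0.072 and its mean 0.00084 while the test pointed downward. Pklr lost its call without knockout replicate 2 or wild type replicate 2 or 3 (limma, adjusted p = 0.071, 0.10 and 0.081), and Slc2a2 without knockout replicate 2 or 3 or wild type replicate 2 or 3 (0.19, 0.12, 0.24 and 0.23). The annotated ends of Pklr and Hcn3 overlap, so reads there belong to either.

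Genes of lipid droplets and PPARγ-linked steatosis passed camera upward (median 0.079; adjusted p = 0.015; adjusted p = 0.70 with an estimated correlation), with none of 18 members past the threshold and 2, Plin4 and Plin5, rising when adjusted over the list alone. Apoa4 stood at 1103 ± 283 FPKM in the knockout and 861 ± 46.7 in wild type, and Cideb at 176 ± 10.1 and 185 ± 23.99. The highest level of the list was in wild type replicate 1 (0.20), against -0.0059 to 0.11 in the knockout. The call was lost without knockout replicate 1 or wild type replicate 2 or 3 (camera, adjusted p = 0.38, 0.14 and 0.11), the median was 0.14 to 0.22 without any of the knockout libraries or wild type replicate 1, and the list was also higher in replicate 1 of both genotypes (camera, adjusted p = 3.6e-04). None of 25 genes of cholesterol synthesis and uptake passed on either count (median -0.082; camera, adjusted p = 0.87). Ebp stood at 78.7 ± 3.61 and 75.0 ± 11.1 FPKM in knockout and wild type. The list was lower in the knockout without knockout replicate 1 (camera, adjusted p = 0.0062; adjusted p = 0.95 with an estimated correlation) and higher in replicate 1 than in the other samples (camera, adjusted p = 1.7e-09). Secreted hepatokines did not differ as a list (camera, adjusted p = 0.89), none of 21 passed, and 1, Gdf15, fell when adjusted over the list alone. Rbp4 stood at 4281 ± 129 and 3734 ± 461 FPKM and Ahsg at 3363 ± 175 and 3258 ± 45.1.

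In bile acid synthesis, the sterol 12-alpha-hydroxylase gene Cyp8b1 rose from 149 ± 32.3 to 291 ± 45.5 FPKM, and 18 of 19 genes did not pass; adjusted over the list alone, 2 rose (camera, adjusted p = 0.59, upward, with a median of -0.013 and a mean of 0.020). Cyp8b1 lost its call without knockout replicate 2 or 3 or wild type replicate 2 or 3 (limma, adjusted p = 0.11, 0.11, 0.18 and 0.17). Among 25 tested xenobiotic P450s Cyp2b10, a target of the receptor CAR, rose from 7.57 ± 2.04 to 21.8 ± 3.98 FPKM (log2 fold change 1.43, SE 0.20; limma, adjusted p = 0.011). Its adjusted p was 0.060 with the replicate as a block and 0.064 without knockout replicate 2 (limma). The other 24 did not pass, and adjusted over the list alone 2 rose and 3 fell. The list did not pass (camera, adjusted p = 0.59) except without knockout replicate 1 (camera, adjusted p = 0.023, downward; adjusted p = 0.40 with an estimated correlation). It was higher in replicate 1 of both genotypes (camera, adjusted p = 0.0011). Glutathione and NRF2 response genes were lower in the knockout: 17 of 21 had a negative fold change, none passed on either count, and the list passed camera (median -0.17; adjusted p = 0.0099; adjusted p = 0.70 with an estimated correlation). Its most abundant members were Mgst1 (2082 ± 172 and 2540 ± 393 FPKM in knockout and wild type) and Gstp1 (1850 ± 804 and 1468 ± 69.8), whose knockout value was 923 FPKM in replicate 1, 2363 in replicate 2 and 2264 in replicate 3. Without knockout replicate 1 Gstp1 was higher in the knockout (limma, adjusted p = 0.030) and the median of the list was -0.27. Levels of the list did not overlap, at -0.19 to -0.011 in the knockout and 0.032 to 0.20 in wild type. The list lost its call without knockout replicate 3 or wild type replicate 1 (camera, adjusted p = 0.11 and 0.19) and was higher in replicate 1 of both genotypes (camera, adjusted p = 3.6e-04).

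Antioxidant enzymes did not differ on either count or as a list (none of 17; camera, adjusted p = 0.91). The contrast of replicate 1 with the other samples was upward (camera, adjusted p = 0.0021), but only the wild type levels followed it. Wild type replicate 1 stood at 0.19 against -0.087 and -0.044 in wild type replicates 2 and 3. Knockout replicate 1 (-0.027) lay between knockout replicates 2 and 3 (0.073 and -0.031). Gpx1 stood at 1951 ± 96.7 and 1902 ± 85.7 FPKM in knockout and wild type, and Cat at 971 ± 93.6 and 912 ± 49.4. In the unfolded protein and integrated stress response Asns fell and 19 of 20 genes did not pass. Those that fell when adjusted over the list alone were 2, Asns and Xbp1 (53.4 ± 7.96 FPKM in wild type, 34.1 ± 3.86 in the knockout). The list did not pass (camera, adjusted p = 0.12), but did without knockout replicate 2 or wild type replicate 1 (camera, adjusted p = 0.016 and 0.033, downward; adjusted p = 0.68 and 0.76 with an estimated correlation). Its median of -0.095 was 0.12 without knockout replicate 1, where the level of the list was lowest (-0.43), while the test still pointed downward (camera, adjusted p = 0.76). It was lower in replicate 1 of both genotypes (camera, adjusted p = 0.0021). Among 7 tested cell cycle genes Cdkn1a rose, over all genes and adjusted over the list alone, and the other 6 did not pass; the median was -0.11, the mean 0.17 and the test pointed upward (camera, adjusted p = 0.86).

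Periportal hepatocyte genes were higher in the knockout (median 0.30; camera, adjusted p = 1.3e-04; adjusted p = 0.26 with an estimated correlation; fry, adjusted p = 0.037). Of 15 tested, 10 had a positive fold change and 5 a negative one. Etnppl, a phospholyase of phosphoethanolamine, rose from 12.3 ± 0.87 to 44.7 ± 0.88 FPKM (log2 fold change 1.78, SE 0.12; limma, adjusted p = 5.6e-05), and 14 of 15 did not pass. Adjusted over the list alone 5 rose, among them the urea cycle genes Cps1 (463 ± 85.9 to 677 ± 49.7 FPKM) and Asl (310 ± 60.3 to 508 ± 10.8). Levels of this list were -0.036 to 0.15 in the knockout and -0.19 to -0.14 in wild type, without overlap. The same held for the female-biased, stellate cell and cholangiocyte lists, none of which passed camera with all samples. The list did not pass in the contrast of replicate 1 with the other samples (camera, adjusted p = 0.97). Pericentral genes did not pass on either count (none of 12; camera, adjusted p = 0.38). Rnase4 stood at 683 ± 109 and 843 ± 34.9 FPKM in knockout and wild type, and Aldh1a1 at 718 ± 89.0 and 729 ± 112.

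Male-biased liver genes moved both ways. Elovl3, a fatty acid elongase, rose from 13.2 ± 1.24 to 31.9 ± 5.62 FPKM, while Hsd3b5 and Nudt7, a peroxisomal coenzyme A hydrolase (271 ± 3.23 to 152 ± 19.3 FPKM), fell, and 12 of 15 did not pass. Adjusted over the list alone, 2 rose and 5 fell. The list did not pass (median -0.29; camera, adjusted p = 0.12) except with the replicate as a block (camera, adjusted p = 0.044), with replicate 1 as a covariate (camera, adjusted p = 0.033) and without knockout replicate 2 or 3 (camera, adjusted p = 0.027 and 0.047). With an estimated correlation it passed in none of these (adjusted p = 0.75 with the block, 0.62 with the covariate, 0.68 and 0.65 without those samples). Its median was -0.14 without knockout replicate 1 and -0.12 without chromosome 4 (camera, adjusted p = 0.76 and 0.75), and its level was -0.61 in knockout replicate 1 against -0.087 and -0.096 in knockout replicates 2 and 3. It was lower in replicate 1 of both genotypes (camera, adjusted p = 0.0022). Elovl3 lost its call without knockout replicate 2 (limma, adjusted p = 0.055), Nudt7 without knockout replicate 3 or wild type replicate 2 or 3 (0.072, 0.085 and 0.10), and Hsd3b5 without knockout replicate 2 or any wild type replicate, up to 0.16. None of 4 tested female-biased genes passed, 2 rose when adjusted over the list alone, and the list passed without knockout replicate 2 or 3 (camera, adjusted p = 0.029 and 0.022, against 0.14; adjusted p = 0.68 and 0.65 with an estimated correlation). That rested on knockout replicate 1, where the level of the list was 0.51 against 0.044 and 0.057 in knockout replicates 2 and 3. The median of 0.25 was 0.046 without that sample, 0.16 without wild type replicate 1, -0.035 without replicate 1 of both genotypes and -0.23 without chromosome 4, while the test still pointed upward (camera, adjusted p = 0.92, 0.22, 0.79 and 0.75). Acnat2 stood at 15.2 ± 2.81 and 8.74 ± 1.23 FPKM in knockout and wild type, and Prlr at 8.99 ± 2.83 and 11.03 ± 1.59. None of 17 circadian clock genes passed, and adjusted over the list alone 2 rose and 1 fell (camera, adjusted p = 0.47). Dbp stood at 29.1 ± 2.73 and 51.9 ± 17.5 FPKM in knockout and wild type.

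Macrophage and Kupffer cell markers were lower in the knockout. Of 16 tested, 15 had a negative fold change with a median of -0.56, and the list passed camera (adjusted p = 4.9e-07; adjusted p = 0.70 with an estimated correlation). Lyz2, the lysozyme of myeloid cells, fell from 31.9 ± 1.27 to 17.3 ± 3.31 FPKM, and the other 15 did not pass. Its adjusted p was 0.082 with the replicate as a block (limma), and 0.088, 0.12, 0.059, 0.15 and 0.17 without knockout replicate 2 or 3 or wild type replicate 1, 2 or 3 (limma). In the test adjusted over the list alone 5 fell, among them Cd74 (150 ± 16.8 FPKM in wild type, 84.3 ± 55.6 in the knockout) and the Kupffer cell gene Clec4f (45.1 ± 1.98 and 29.9 ± 7.85). Knockout replicate 1 (0.18) lay within the wild type levels of the list (0.15 to 0.32), while knockout replicates 2 and 3 lay at -0.30 and -0.65. Without knockout replicate 3 the median was -0.33. The contrast of replicate 1 with the other samples was upward (median 0.29; camera, adjusted p = 5.3e-04), but only the knockout levels followed it. Wild type replicate 1 (0.15) had the lowest wild type level, below 0.32 in wild type replicates 2 and 3. Sinusoidal endothelial markers were lower too: 13 of 14 had a negative fold change (median -0.34; camera, adjusted p = 4.6e-04; adjusted p = 0.70 with an estimated correlation) and none passed on either count. Clec4g stood at 35.8 ± 8.07 and 28.4 ± 2.06 FPKM in knockout and wild type, and Fcgr2b at 22.3 ± 7.43 and 28.9 ± 2.08. The level of the endothelial list in knockout replicate 2 (0.059) lay above that in wild type replicate 1 (0.047), so the genotypes overlapped.

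Markers of other cell types did not pass as lists. None of 11 stellate cell and fibrosis genes passed on either count (camera, adjusted p = 0.42), with Dcn at 63.0 ± 1.04 and 73.8 ± 8.69 FPKM in knockout and wild type and Rgs5 at 11.3 ± 1.25 and 12.3 ± 1.46. None of 3 tested lymphocyte and neutrophil genes passed on either count (camera, adjusted p = 0.73, upward, median -0.028, mean 0.0079). S100a9 stood at 4.37 ± 2.45 and 5.06 ± 4.44 FPKM and S100a8 at 4.29 ± 4.07 and 4.74 ± 4.78, and the list was higher in replicate 1 of both genotypes (camera, adjusted p = 0.0099). None of 3 tested cholangiocyte genes passed (camera, adjusted p = 0.59) and 1, Spp1 (27.0 ± 4.44 to 18.3 ± 1.35 FPKM), fell when adjusted over the list alone, while Krt23 stood at 5.91 ± 2.98 in the knockout and 6.27 ± 1.75 in wild type. Among 5 red blood cell genes Alas2 fell, over all genes and adjusted over the list alone, and 4 did not pass. That list had a median of 0.080, a mean of -0.33 and a test pointing downward (camera, adjusted p = 0.42), and it was higher in replicate 1 of both genotypes (camera, adjusted p = 0.0022). Adipose tissue and pancreas lists had 1 tested gene each, Car3 (698 ± 65.9 and 814 ± 198 FPKM in knockout and wild type) and Cela1 (27.8 ± 6.05 and 34.8 ± 9.44), and neither passed on either count.

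Acute phase genes were lower in the knockout: 17 of 21 had a negative fold change, with a median of -0.27, and the list passed camera (adjusted p = 0.0047; adjusted p = 0.70 with an estimated correlation). The level of the list in knockout replicate 1 (0.063) lay within the wild type levels (0.0105 to 0.16). Orm3 fell and 20 did not pass. With p adjusted over the list alone 2 fell, Orm3 and Orm1 (690 ± 175 FPKM in wild type, 379 ± 75.6 in the knockout), neighbouring and similar genes on chromosome 4. The call of the list was lost without knockout replicate 3 or wild type replicate 1 (camera, adjusted p = 0.10 and 0.19), where the median was -0.12 without the latter, and with chromosome 4 left out (camera, adjusted p = 0.11). The list was higher in replicate 1 of both genotypes (camera, adjusted p = 1.3e-06). Orm3 itself was not past the threshold without knockout replicate 2 or 3 or any wild type replicate (limma, adjusted p = 0.057 to 0.17).

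**Figure D2:**
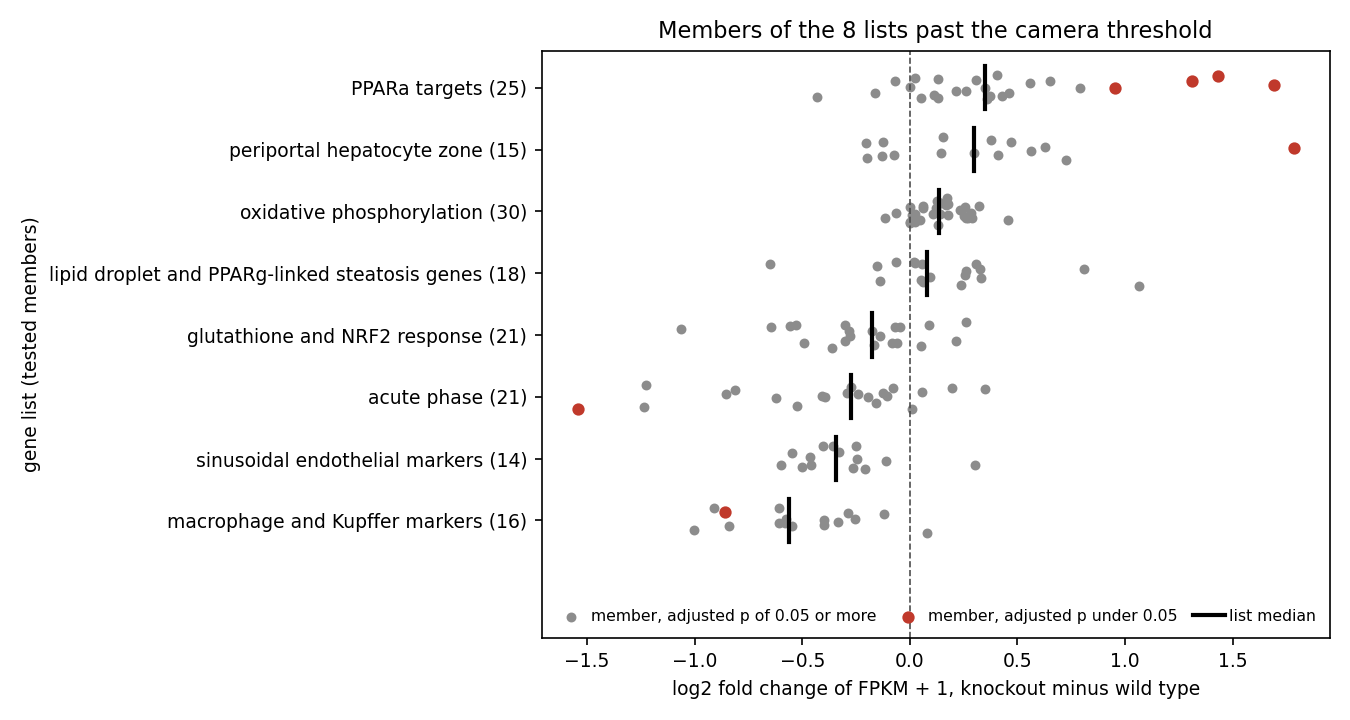
Log2 fold change (knockout minus wild type, FPKM + 1) of each tested member of the 8 lists past the camera threshold, with members past adjusted p of 0.05 in red, other members in grey and black bars at the list medians. Medians run from -0.56 for macrophage and Kupffer markers to 0.35 for PPARα targets, and most members of each list are grey.

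**Figure D3:**
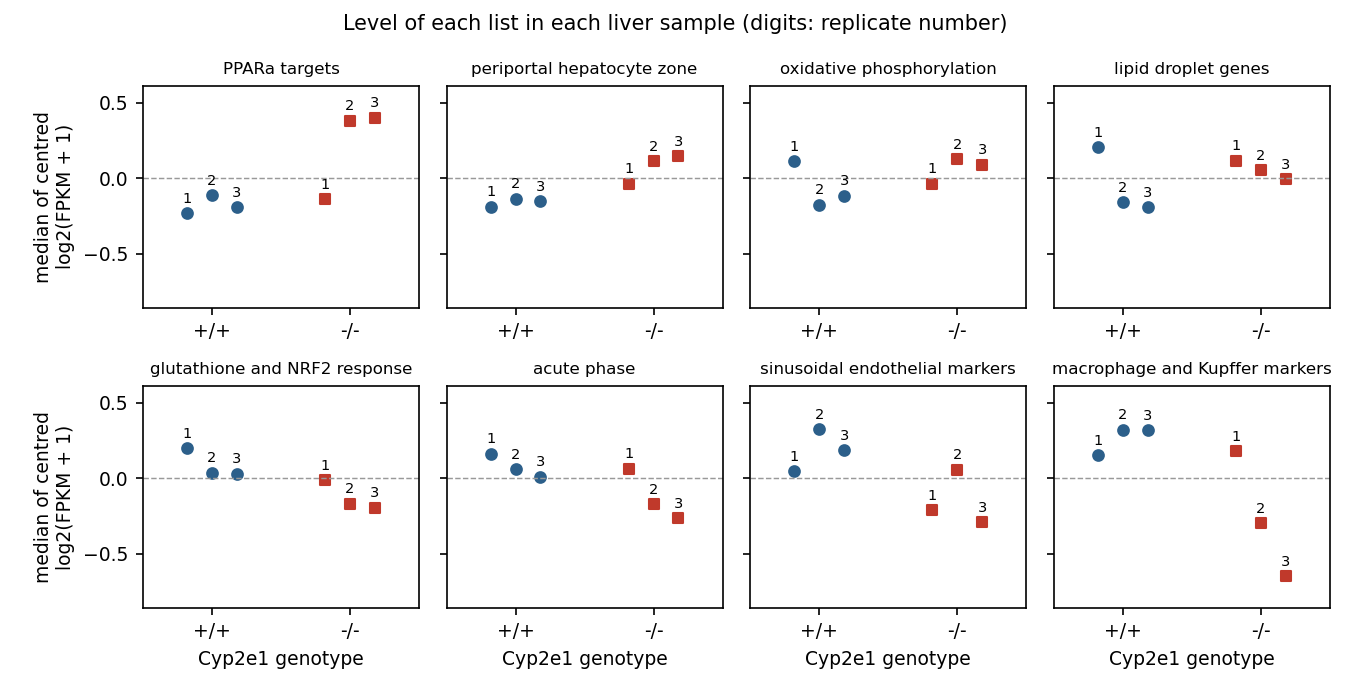
Level of the same 8 lists in each liver, as the median over members of log2(FPKM + 1) minus the gene's mean over all samples, with wild type in blue, knockout in red and the replicate number above each point. Knockout replicate 1 lies among or near the wild type points for PPARα targets (-0.14) and macrophage markers (0.18), and of the 8 lists only the periportal and the glutathione and NRF2 lists separate the genotypes.

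Genes near the targeted locus were also listed. None of 23 tested neighbours of Cyp2e1 on chromosome 7 passed on either count (median 0.010; camera, adjusted p = 0.73), with Ifitm3 at 336 ± 91.8 and 337 ± 30.2 FPKM in knockout and wild type and Rplp2 at 226 ± 23.4 and 197 ± 39.7. The list was higher in the knockout without wild type replicate 1 (camera, adjusted p = 0.027; adjusted p = 0.55 with an estimated correlation). The contrast of replicate 1 with the other samples was upward (camera, adjusted p = 3.6e-04), but only the wild type levels followed it. Wild type replicate 1 stood at 0.16 against -0.11 and -0.093 in wild type replicates 2 and 3. Knockout replicate 1 (-0.017) lay between knockout replicates 2 and 3 (0.014 and -0.030). Elsewhere the genes that changed lay close together. On chromosome 2, 10 of 12 tested genes between 175918283 and 178035859 rose, among them Zfp970, Zfp971 and Zfp966, all zinc-finger or unnamed genes that share sequence. These bounds are those of the first and last gene that rose there, which raises the share. Among 76 genes 33 had another within 2 Mb, against a median of 15 in 10000 random draws of tested genes (permutation p = 0.0003).

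**Figure D4:**
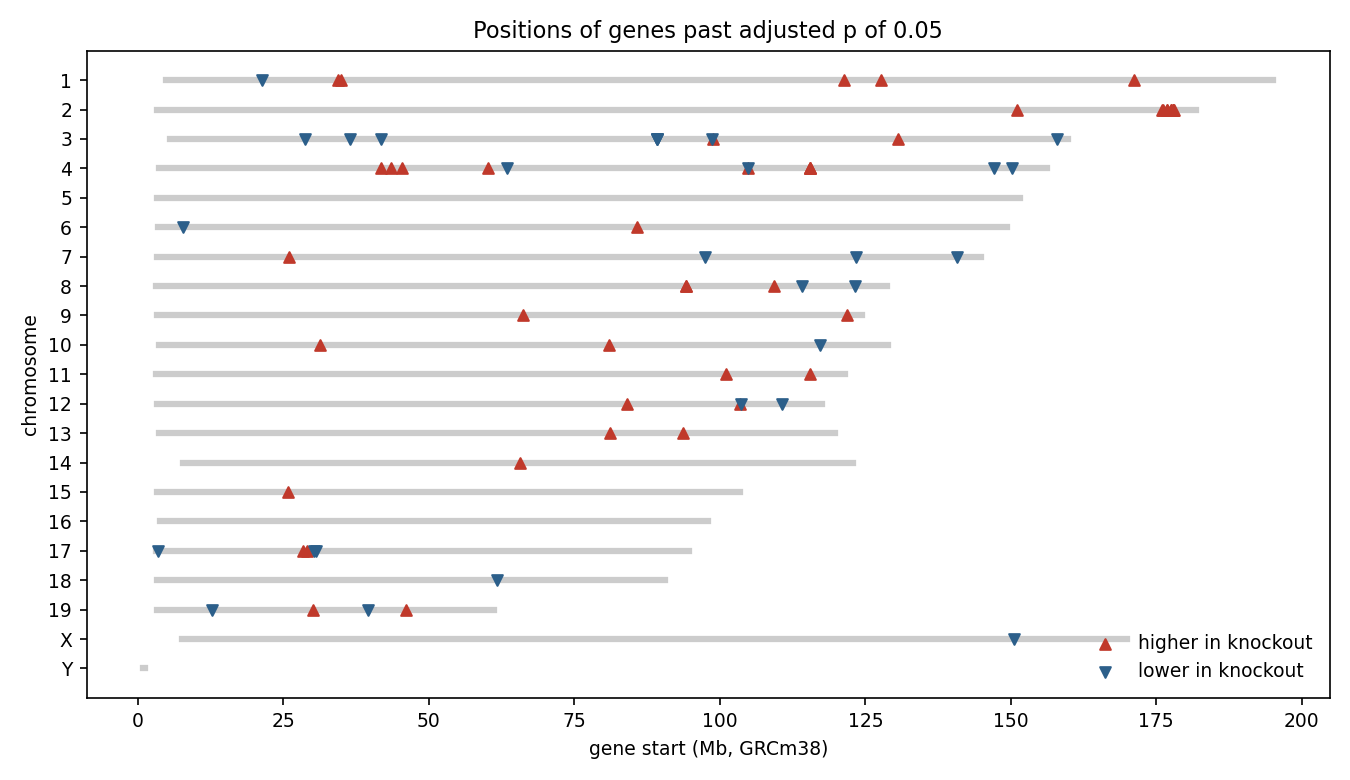
Start positions in Mb (GRCm38) of the 76 genes past the threshold along each chromosome, with upward red triangles for genes higher and downward blue triangles for genes lower in the knockout; grey bars span the tested genes. The stack of red triangles at the end of chromosome 2 holds 10 genes.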

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

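Equal sums, replicate 1 as a covariate, replicate 1 of both groups left out and chromosome 4 left out were chosen after the data were seen; the other alternatives were planned. Tests on counts and count normalizations were not run, as the table holds FPKM. All 76 genes kept their direction under every alternative that tested them, and Cyp2e1 stayed between -4.70 and -4.53 (limma, adjusted p = 1.5e-11 to 3.3e-05). In all 76 the knockout and wild type values did not overlap, so only median-ratio scaling or equal sums could have turned a direction. The kept directions are therefore little evidence of robustness. Of 29 named genes past the threshold, 14 passed under every alternative and 15 whichever sample was left out. The count of 76 (47 higher, 29 lower) became 32 (25, 7) with no filter on low values, 30 (20, 10) with a mean of at least 5 FPKM, 30 (23, 7) against a minimum change of 1.2-fold, 1151 (597, 554) with sample quality weights, 174 (89, 85) with replicate 1 as a covariate and 1183 (690, 493) without replicate 1 of both groups. With 1 sample left out it ranged from 29 to 211, with 21 to 124 higher and 8 to 87 lower. It was 72 with the replicate block (58 genes shared), 64 with a pseudocount of 0.1, 68 with median-ratio scaling, 71 with equal sums and 61 without chromosome 4. The stricter settings test a harder null, more genes or fewer genes; the cause of the other shifts was not tested.

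No filter ended the calls of 14 named genes, the minimum change those of 11, a mean of at least 5 FPKM those of 6, median-ratio scaling those of 4, a pseudocount of 0.1 those of 3 and equal sums that of Slc2a2. Named genes not past the threshold with all samples also gained calls (limma, adjusted p). With sample quality weights these were Dbp (0.017), Acnat2 (0.011), Prlr (0.042), Rnase4 (0.022) and Spp1 (0.012), with replicate 1 as a covariate Spp1 (0.045), without knockout replicate 1 Gstp1 (0.030), and without replicate 1 of both groups Acaa2 (0.038), Mgst1 (0.033), Gstp1 (3.2e-04), Rbp4 (0.0093), Dbp (0.020), Acnat2 (0.024), Rnase4 (0.0024) and Spp1 (0.018). The replicate block ended the calls of Cyp2b10, Slc2a2 and Lyz2 and brought the male-biased list past the threshold (camera, adjusted p = 0.044; adjusted p = 0.75 with an estimated correlation), and it changed no other call of a named gene or list. Of the 8 lists past camera, 0 passed with an estimated correlation and 1 (periportal) with fry. No list passed with an estimated correlation under the alternatives that tested lists either (lowest adjusted p = 0.11, without knockout replicate 1). These failures cannot be read as an effect of gene correlation alone, as that form has little power with 6 samples. The periportal list had an estimated correlation of -0.014, below the preset 0.01. Its adjusted p still went from 1.3e-04 to 0.26 (camera). Replicate 1 as a covariate brought the male-biased list past the threshold (camera, adjusted p = 0.033), and no filter, sample quality weights and leaving out replicate 1 of both groups the beta-oxidation list (camera, adjusted p = 0.049, 0.0044 and 0.0035). Medians of lists past camera that moved by over 1.5 times were, with weights, 0.24 (oxidative phosphorylation) and 0.18 (lipid droplets), without replicate 1 of both groups 0.28, 0.18 and 0.52 (these and PPARα targets), with no filter -0.36 (macrophages), with a pseudocount of 0.1 -0.28 (glutathione) and with a mean of at least 5 FPKM 0.15 (lipid droplets). A mean of at least 5 FPKM ended the calls of the glutathione and lipid droplet lists (camera, adjusted p = 0.079 and 0.067).

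Every result that turned its direction had not been past the threshold and did not pass in the other direction. For genes the log2 fold changes after turning were 0.018 (Aldh1a1), 0.0002 (S100a9) and 0.0034 (Ifitm3) with median-ratio scaling. With sample quality weights they were 0.0049 (Cideb), 0.0097 (Aldh1a1), 0.095 (S100a9), 0.20 (S100a8), 0.021 (Krt23) and 0.022 (Cela1), and without replicate 1 of both groups 0.0052 (Aldh1a1), 0.18 (S100a9), 0.073 (Krt23) and 0.059 (Cela1). Over all runs with 1 sample left out, those that kept the direction included, the ranges were -0.022 to 0.17 (Acaa2), -0.030 to 0.18 (Ebp), -0.022 to 0.66 (Gstp1), -0.0043 to 0.067 (Gpx1), -0.13 to 0.037 (Cideb), -0.077 to 0.15 (Cox4i1), -0.12 to 0.10 (Aldh1a1), -0.38 to 0.53 (S100a9), -0.73 to 0.52 (S100a8), -0.39 to 0.28 (Krt23) and -0.24 to 0.098 (Ifitm3). Lists turned at these adjusted p (camera): antioxidant enzymes 0.89 without chromosome 4, 0.96 with median-ratio scaling, 0.35 with weights and 0.44 without replicate 1 of both groups; cholesterol synthesis 0.88 with a mean of at least 5 FPKM; cholangiocytes 0.80 with no filter; glucose metabolism 0.96 with no filter, 0.86 with the replicate block, 0.86 with replicate 1 as a covariate, 0.76 with weights and 0.67 without replicate 1 of both groups; glucose metabolism and cell cycle 0.998 with a pseudocount of 0.1. With weights hepatokines, red blood cells and cell cycle each turned at 0.87, and without replicate 1 of both groups hepatokines at 0.95 and cell cycle at 0.74. For lists that turned in some runs with 1 sample left out, adjusted p over all such runs ranged over 0.0062 to 0.57 (cholesterol), 0.023 to 0.996 (xenobiotic P450s), 0.19 to 0.76 (antioxidant enzymes), 0.71 to 0.996 (glucose), 0.61 to 0.98 (hepatokines), 0.050 to 0.87 (red blood cells), 0.50 to 0.996 (cell cycle), 0.19 to 0.97 (lymphocytes and neutrophils) and 0.027 to 0.94 (neighbours of Cyp2e1). The lowest values for cholesterol, xenobiotic P450s and the neighbours came from runs that kept the direction. The cause was not tested. With 9.21 to 12.1 M fragments estimated per library, genes under 1 FPKM rest on few fragments, and their fold changes grow with the smaller pseudocount, as for Zfp971 (1.86 to 4.01) and Psmc3ip (1.86 to 3.15).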

Other observations

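The tests of sequence sharing, chromosome segments, transcript length, feeding or stress state, sequencing depth and other splits by gene count were chosen after the result was seen, as were the settings without chromosome 4 or replicate 1 and the genes in the next paragraph.

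Several abundant enzymes outside the lists differed between the genotypes. Bhmt, which remethylates homocysteine with betaine, rose from 1206 ± 107 to 2880 ± 515 FPKM (log2 fold change 1.24, SE 0.16; limma, adjusted p = 0.0053), and Gldc, of glycine cleavage, from 27.3 ± 3.78 to 53.9 ± 3.21 (limma, adjusted p = 0.0099). Cth, which makes cysteine from cystathionine, fell from 102 ± 23.7 to 55.5 ± 2.18 FPKM (limma, adjusted p = 0.048). Insig2, which retains the sterol sensor in the endoplasmic reticulum, rose from 34.4 ± 1.55 to 70.1 ± 3.25 FPKM (limma, adjusted p = 0.0026). Mt1, the neighbour of Mt2, rose from 143 ± 68.7 to 427 ± 118 FPKM (limma, adjusted p = 0.039). With the genotype in the model Mt1 was also higher in replicate 1, by 0.87 on the log2 scale (limma, adjusted p = 0.020). The chaperone gene Hsp90aa1 fell from 125 ± 29.4 to 61.1 ± 2.84 FPKM (limma, adjusted p = 0.028). Next to C8a, C8b, which encodes the beta chain of the same complement component, fell from 226 ± 34.6 to 105 ± 5.57 FPKM (limma, adjusted p = 0.0053). The clock gene Arntl stood at 1.10, 1.81 and 1.04 FPKM in the knockout libraries and 0.37, 0.28 and 0.22 in the wild type, and missed the threshold (limma, adjusted p = 0.077).

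The real split of the 6 samples gave 76 genes and the highest of the other 9 gave 1, and 1 of 10 splits reached 76. For the lists the real split gave 8 past camera, the highest other gave 12 (knockout replicates 1 and 2 with wild type replicate 1 against the rest), and 3 of 10 splits reached 8. With 10 splits the share cannot fall under 0.05, so the gene count cannot decide. For the lists that limit does not matter, as a split that mixed the genotypes put more lists past camera than the real one. The number of lists past camera at the preset correlation thus does not set the genotype apart from other groupings. The other 3 splits that part all same-numbered pairs gave 0 genes each, and 2, 4 and 7 lists.

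The genes that changed lay close together in the genome. Reads shared between similar gene copies are argued against as the whole cause: with neighbours that share at least 5% of their 31-base words counted once, 22 of 66 genes still had a neighbour within 2 Mb, against a median of 11 in random draws (permutation p = 0.0099). Joint regulation of neighbours, by the state of the animal or by the genotype, as may hold for Mt1 and Mt2 or the Cyp4a genes, stays open: the 74 genes most changed with replicate 1, counted the same way, had 10 such neighbours against a median of 14 (permutation p = 0.859), but that contrast followed transcript length (Spearman rho -0.52) and cannot stand for the state of the animals. A candidate explanation that also stays open is that some chromosome segments came from different parental strains in the 2 groups, for which 22 genes with a neighbour are what it needs but no sequence was examined. It is a hypothesis only and cannot be told apart from joint regulation by these counts, and the labels give C57BL/6 for both genotypes and none of 23 tested neighbours of Cyp2e1 itself passed.

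PPARα targets were higher in the knockout by camera at the preset correlation, though knockout replicate 1 (-0.14) lay among the wild type levels (-0.23 to -0.11). The upward median was not confined to chromosome 4, which holds the Cyp4a genes. Without that chromosome the median log2 fold change of the list was 0.285 (camera, adjusted p = 1.0e-04, or 0.80 with an estimated correlation). A segment effect there stays open as the source of the calls of Cyp4a10, Cyp4a14 and Cyp4a31. The difference of replicate 1 from the other samples was not put to a test by this comparison. Each genotype holds 1 replicate 1 sample, so only a shift of equal size in both cancels between the genotypes. For this list the shift was larger in the knockout. Knockout replicate 1 stood at -0.14 against 0.38 and 0.40 in knockout replicates 2 and 3. Wild type replicate 1 stood at -0.23 against -0.11 and -0.19 in wild type replicates 2 and 3. The list was lower in replicate 1 (median -0.28; camera, adjusted p = 0.035), and its median without those samples was 0.52. An effect of the Cyp2e1 genotype on PPARα activity stays open as a hypothesis, and camera with an estimated correlation did not separate the list from other genes (adjusted p = 0.70). The camera call held whichever sample was left out and under the other settings at the preset correlation (adjusted p = 1.7e-11 to 1.0e-04).

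Replicate 1 of both genotypes differed from replicates 2 and 3, with 74 genes higher and 374 lower in limma with the genotype in the model, 448 in all against 184 with transcript length removed. Fgl1 stood at 310 and 252 FPKM in knockout and wild type replicate 1 against 90.9 to 117 in the other samples, and Derl3 at 1.39 and 1.72 against 13.3 to 17.7. Sequencing depth is argued against, since the relative depth of wild type replicate 1 was 0.972, just below replicates 2 and 3 of both genotypes (0.978 to 1.04), while that of knockout replicate 1 was 1.28, above them. A length bias from RNA quality or library preparation may contribute, as the difference followed transcript length across 9883 genes (Spearman rho -0.52, with genes not independent), and so may a difference in feeding or stress state, as cholesterol synthesis genes stayed higher with length removed (camera, adjusted p = 6.1e-11; adjusted p = 0.26 with an estimated correlation), and the 2 stay open together. Among the 76 genes that differed with genotype, 2 also differed with replicate 1, against 448 of all 9968 tested genes. So small an overlap does not show that the genotype calls are free of the replicate 1 difference.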
